A study of Mus musculus with 12 samples.

How the data were processed

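Gene expression was measured in subcutaneous Colon26 tumours of BALB/c wild-type mice. Colon26 is a mouse colon carcinoma line. Per the labels' protocols, tumours were digested with collagenase and DNase I, tumour cells and dead cells were reduced on a Percoll layer, and polyadenylated RNA of the remaining total cells was amplified. The libraries were of the serial analysis of gene expression type that reads the 5′ end of each transcript, run on an Ion S5 sequencer. Each sample came from the tumour of a separate implanted mouse, per the labels, so the spread between the 3 samples of a group includes the spread between animals. The 12 samples formed 4 groups of 3: control, minP1 (an immunostimulatory peptide of the chromatin protein HMGN1), anti-PD-L1 (an antibody against the checkpoint ligand PD-L1), and both treatments together. The labels of the combined group name the peptide in the sample title only. Their treatment field holds a plus sign before the antibody and no peptide. The group was taken from the title, so every result of the combination rests on that title.

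The deposited values were whole-number counts per gene symbol, 1 table per sample, with 19921 symbols each and no normalization. Per the submitters' processing notes, Bowtie2 2.2.5, R 3.6.1, DESeq2 and the mouse build mm10 were used. The notes give neither the role of each tool nor the DESeq2 version, and the counting tool, its annotation, its treatment of strand and its handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies, antisense neighbours or overlapping neighbours are therefore uncertain. A 5′ tag gives 1 read per captured transcript end, so no correction for transcript length was made. No molecular identifiers are recorded, so reads are not independent molecules, and intervals and floors cover counting error only.

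Totals ranged from 133917 to 473273 counts, a 3.53-fold range, with the lowest totals in the combined group. Genes were kept with the filterByExpr rule of edgeR at its defaults, which left 5443 genes holding 89.8% to 93.6% of each library's counts, and 14478 were not tested. Counts were scaled with trimmed mean of M-values (TMM) factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 12 samples with 1 mean per group, and Benjamini-Hochberg adjustment over the 5443 genes in each of 6 comparisons, with a threshold of 0.05. The common dispersion was 0.0506, a biological coefficient of variation of 22.5%. Log2 fold changes used a prior count of 0.125. The 6 comparisons were each treatment against control, the combination against each lone treatment, and the interaction, defined as the change from anti-PD-L1 to the combination minus the change from control to minP1. An exact permutation test of 3 samples against 3 cannot give a p-value under 0.1, so none was used for genes. Where every library of a group was at 0, the fold is given as a bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% exact counting interval.

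The comparisons, tests, alternatives, gene lists and the rule for naming genes were written before the data were examined. The rule took, per comparison, up to 10 genes in each direction with the largest log2 fold change among those that passed, reached a mean of 10 CPM in a group and had no overlap between groups. It added up to 4 members of each list by smallest p, and 9 genes of interest whether changed or not (Hmgn1, Tlr4, Cd274, Pdcd1, Cd8a, Ifng, Gzmb, Cxcl9 and Il12b). Where fewer than 5 genes passed, it took the 5 smallest p-values in each direction. Not every gene taken is named. Genes outside the rule are said to be chosen after their values were seen.

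The 28 fixed lists held 399 different genes, of which 353 are in the tables. They were pan-T cell, CD8 and cytotoxic, regulatory and helper T, T cell checkpoint, NK cell, B and plasma cell, neutrophil, inflammatory monocyte, macrophage, conventional dendritic, mature dendritic, plasmacytoid dendritic, mast cell with basophil and eosinophil, MHC class I, MHC class II, type I interferon, interferon gamma, TLR and NF-kB, immunosuppressive myeloid, cell cycle, hypoxia and glycolysis, epithelial and carcinoma, fibroblast and matrix, endothelial, skeletal muscle, adipocyte and keratinocyte, erythroid and platelet, and dissociation and heat stress. The 12 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, adjusted over the 12 lists within a comparison. Camera compares a list with the other genes. The filter keeps genes that are high in a group, so the tested members are partly sorted by their change. The same lists were tested with a correlation estimated from the data and with fry, which tests whether the list's genes move one way on balance. No list passed in any of the 6 comparisons with an estimated correlation. A further test of the counts summed over all members of each of the 28 lists, adjusted over the 28, was added after the data were seen, as was the same test on the members not tested one by one.

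Alternatives were median-of-ratios and upper-quartile scaling, no filter on low counts, a filter at a mean of 10 CPM in at least 1 group, DESeq2 1.42.0, limma voom with sample weights (statmod 1.5.0), a replicate block, thinning to the smallest library, fits of the 6 samples compared, and leaving out each replicate. The filter at 10 CPM was planned as a stricter filter. At these depths it kept 10067 genes, more than filterByExpr. Added after the data were seen were the level of Bc1 or the number of genes detected as a covariate, the removal of minP1 replicate 2 with anti-PD-L1 replicate 1, and the removal of ribosomal RNA, Bc1, Lrrc17, mitochondrial and ribosomal protein genes. Overlaps between comparisons that share the controls were set beside 40 simulations in which all 4 groups had the same means. The first 100 bases of transcripts in GENCODE M21 (GRCm38, the same assembly as mm10) were compared with blastn 2.17.0, and coordinates are from that annotation. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. All 12 deposited tables were used.

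The main test was tested on simulated counts with 200 changed genes among 5443, 5 times per comparison. The changed genes were drawn only from genes with a control mean over 20 CPM, so the shares recovered do not cover genes lower in control. For minP1 against control, 28.6% of 2-fold and 88.8% of 4-fold changes were recovered. For the combination against control these shares were 22% and 77.4%. For the interaction they were 5.2% and 47.4%. False calls made up 2.8% to 5.4% of the calls on average over the 6 comparisons. A 1.6-fold change of the MHC class I list, simulated for minP1 against control, was called in 20 of 20 simulations, and 3 of 220 tests of other lists were called. Simulated genes were drawn independently, while the correlation estimated from the data was 0.4 for that list. The simulation therefore does not give the rate of false list calls among correlated genes.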

Results

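The series asked how minP1, a peptide of HMGN1 that stimulates immune cells, and an antibody against PD-L1 change the cells of a tumour when given alone or together. Mice received 200000 Colon26 cells in the right flank. Anti-PD-L1 antibody (200 µg, intraperitoneal) was given on days 4 and 8, minP1 (0.08 µg, intraperitoneal) on day 9, and tumours were taken on day 10. Total tumour cells left after the tumour-cell and dead-cell reduction were profiled by 5′-end tag sequencing, with 3 mice in each of 4 groups. Adjusted p-values of genes are from edgeR's quasi-likelihood test and those of lists from camera, both with Benjamini-Hochberg adjustment. A value after ± is the SE of a log2 fold change or the SD of a level over the 3 libraries of a group.

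Libraries were shallow and unequal in depth. Total counts were 378077 ± 93793 in control, 303587 ± 24308 in minP1, 266582 ± 70048 in anti-PD-L1 and 168872 ± 31806 in the combination. Genes detected at equal depth numbered 11072 ± 511, 10774 ± 273, 10329 ± 358 and 10081 ± 329 in the same order. Ribosomal RNA took 3.04% ± 0.753 of control counts and 1.03% ± 0.172 of combination counts. Bc1, a small noncoding RNA (chromosome 7, 144914470 to 144914637, plus strand, GRCm38), and Lrrc17, whose sequence matches 91 of the first 100 bases of Bc1 at 97.8% identity, took nearly equal counts in each library, so their reads may be shared. Together they took 1.86% ± 0.488 of counts in control, 2.53% ± 1.43 in minP1, 3.45% ± 1.04 in anti-PD-L1 and 4.62% ± 1.95 in the combination. The first principal component held 49.7% of the variance and placed the combination farthest from control. On that component minP1 replicate 2 (-0.21) stood apart from minP1 replicates 1 and 3 (-22.45 and -24.45), and anti-PD-L1 replicate 1 (17.31) from replicates 2 and 3 (-5.03 and -8.39). These libraries held the highest Bc1 and Lrrc17 shares of their groups, 4.17% and 4.42%.

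**Figure D1:**
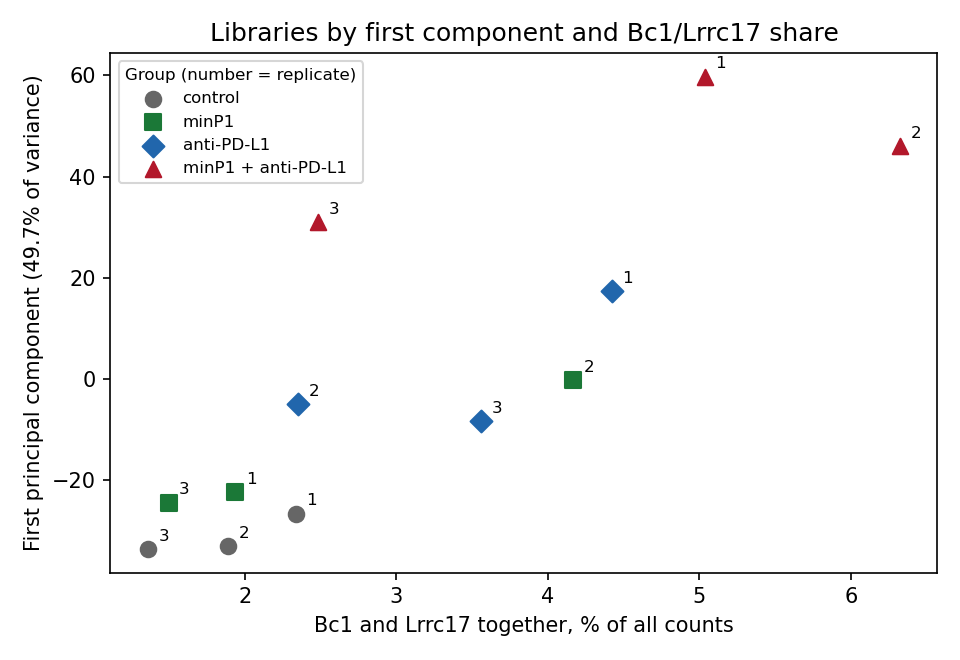
Each point is 1 library, with its share of counts from Bc1 and Lrrc17 (%) on the horizontal axis and its position on the first principal component (arbitrary units, 49.7% of the variance) on the vertical axis. The 3 combination libraries lie between 30.92 and 59.75 on the component, above the other 9.

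Hmgn1, the gene that minP1 is derived from (chromosome 16, 96120618 to 96127729, minus strand), was measured at 561 ± 103 CPM in control, 545 ± 93 in minP1, 725 ± 199 in anti-PD-L1 and 912 ± 211 in the combination. It passed the test in the combination against control (0.70 ± 0.25, adjusted p = 0.0329) and against minP1 (0.74 ± 0.25, adjusted p = 0.0392). Both calls were lost without the filter on low counts (0.64 ± 0.26, adjusted p = 0.105, and 0.66 ± 0.26, adjusted p = 0.139). In the first comparison 2 of 3 combination libraries lay above every control, and with the Bc1 level as a covariate the difference was 0.12 ± 0.26 (adjusted p = 0.786). Several immune genes named in advance did not pass the filter on low counts. Summed over the 12 libraries, Tlr4 (a receptor for HMGN1) had 46 counts, Cd274 (PD-L1) 30, Pdcd1 (PD-1) 3, Cd8a 7, Ifng 2, Gzmb 25, Cxcl9 74 and Il12b 10. Tested without that filter none of the 8 passed in any comparison, and the smallest adjusted p was 0.0748, for Cxcl9 in the combination against control (-1.92 ± 0.73, edgeR).

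The first comparison asked what minP1 alone did 1 day after its injection. Genes for loading peptides onto MHC class I tended to be higher in minP1 tumours, although no gene alone passed the test. H2-K1, a class I heavy chain (chromosome 17, 33996017 to 34000347, minus strand), stood at 1736 ± 501 CPM in control and 3174 ± 462 CPM in minP1, above every control in 3 of 3 libraries (0.87 ± 0.25, adjusted p = 0.411). B2m, the class I light chain, differed by 0.71 ± 0.26, the peptide transporter Tap1 by 0.98 ± 0.33 and its partner Tapbp by 0.78 ± 0.28. As a list, MHC class I presentation was higher than other genes with a mean log2 fold change of 0.64 over 13 members, 11 of them positive (camera, adjusted p = 7.93e-08; adjusted p = 0.406 with an estimated correlation). No member passed over all genes, and 6 passed, all higher, when adjusted over the list alone. The interferon gamma response list had a mean of 0.86 over 11 members, all positive (camera, adjusted p = 1.03e-06; adjusted p = 0.414 with an estimated correlation), with 0 members passing either way. Among its members, the transcription factor Irf1 differed by 1.0 ± 0.32 and the chemokine Cxcl10 by 0.64 ± 0.34. H2-K1 belongs to a family of similar genes, and its counts may include reads of relatives.

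Leading genes outside these lists were few, and none passed. The metal-binding protein Mt1 was 1.06 ± 0.25 log2 units above control and the splicing factor Prpf19 differed by -1.87 ± 0.42 (adjusted p = 0.287 for both, edgeR). F10, coagulation factor X, differed by 1.62 ± 0.46, the B cell factor Pax5 by 2.03 ± 0.68, the T cell surface protein Thy1 by 0.93 ± 0.37 and the granule protease Gzma by 0.90 ± 0.40. The mannose receptor Mrc1 of macrophages differed by -0.88 ± 0.31. The beta-globin Hbb-b2, which has a near-identical copy, differed by -1.80 ± 0.44.

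In all, edgeR called 0 of 5443 genes in minP1 against control, with 383 at an unadjusted p under 0.05 where chance gives 272. DESeq2 called 1 gene, and limma voom 0. Of all genes tested, 12.4% had no overlap between the groups, where chance gives 10%. Without a filter on low counts 51 genes passed, with the Bc1 covariate 1, without control replicate 3 the count was 5 and without minP1 replicate 3 it was 1. The 10 other lists did not pass camera, with means of 0.07 for neutrophil, 0.39 for monocyte, 0.39 for MHC class II, 0.33 for type I interferon, 0.05 for TLR and NF-kB, -0.08 for cell cycle, -0.19 for fibroblast and -0.14 for dissociation stress. Macrophage (mean -0.05, median 0.02) and hypoxia (mean 0.01, median -0.07) also did not pass, and their means and medians differed in sign. Of the monocyte genes 2 were higher when adjusted over the list alone. With the Bc1 covariate MHC class II passed (mean 0.60, 0.00416; adjusted p = 0.493 with an estimated correlation). Without control replicate 1 the means of both called lists were 0.42, with adjusted p-values of 0.0012 for MHC class I and 0.0278 for interferon gamma. Without control replicate 3, which held 622 counts of the interferon gamma list in 473273 counts against 117 in 375204 and 141 in 285753 in replicates 1 and 2, the interferon gamma mean was 1.41.

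The second comparison was anti-PD-L1 alone against control. Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499, plus strand), rose from 17.9 ± 16.4 to 145 ± 66 CPM (2.78 ± 0.46, adjusted p = 0.00496, edgeR). Mt1 rose by 1.80 ± 0.25, the activating Fc receptor Fcgr4 by 1.86 ± 0.38, the glucose transporter Slc2a1 by 1.51 ± 0.31 and Arrdc3 by 1.68 ± 0.38. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361, minus strand) fell by 1.32 on the log2 scale (SE 0.33, adjusted p = 0.0458), from 115 ± 20 to 47.2 ± 15.9 CPM. Prpf19 (-2.98 ± 0.51), Hbb-b2 (-2.69 ± 0.51), the acyl-CoA binding protein Dbi (-2.28 ± 0.46) and the calmodulin gene Calm2 (-1.97 ± 0.44) also fell. Each of these genes had no overlap between the groups.

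MHC class I genes were also higher with the antibody. H2-K1 (1.20 ± 0.25), B2m (1.14 ± 0.26) and Tap1 (1.44 ± 0.33) passed over all genes, and 7 of 13 members passed when adjusted over the list alone, all higher. The list mean was 0.77 (camera, adjusted p = 6.56e-06; adjusted p = 0.249 with an estimated correlation). The interferon gamma list had a mean of 1.03 (adjusted p = 2.95e-05; adjusted p = 0.25 with an estimated correlation). Irf1 rose by 1.28 ± 0.32 (edgeR, adjusted p = 0.05, under the threshold before rounding), and 2 of the 11 members passed when adjusted over the list alone. The mean was 0.60 without control replicate 1 and 1.57 without control replicate 3. Inflammatory monocyte genes had a mean of 0.84 (adjusted p = 0.00172; adjusted p = 0.14 with an estimated correlation). No monocyte member passed over all genes. Adjusted over the list alone 5 were higher and 1 lower, among them Ly6a (1.33 ± 0.37), Ly6c2 (1.16 ± 0.36) and F10 (1.38 ± 0.47).

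Neutrophil genes had a mean of 0.62 (adjusted p = 0.0472; adjusted p = 0.249 with an estimated correlation) with members in both directions. The chemokine receptor Cxcr2 fell by 1.02 (SE 0.25, adjusted p = 0.0422), while S100a9 was at 1.41 ± 0.49 (adjusted p = 0.13). Adjusted over the list alone 1 member was higher and 1 lower. The neutrophil call was lost without control replicates 1 or 2 (adjusted p of 0.117 and 0.127) and without anti-PD-L1 replicates 1 or 2 (0.0835 and 0.159). The lists that did not pass had means of 0.21 for macrophage, 0.32 for MHC class II, 0.33 for type I interferon, 0.36 for TLR and NF-kB, -0.13 for cell cycle and -0.07 for dissociation stress. Hypoxia (mean 0.01, median -0.2) and fibroblast (mean -0.31, median 0.01) did not pass and differed in sign between mean and median. With the Bc1 covariate hypoxia (0.41, 0.0126), MHC class II (0.83, 0.00241) and TLR and NF-kB (0.54, 0.0045) passed as higher lists (adjusted p = 0.274, 0.24 and 0.0973 with an estimated correlation). In the TLR and NF-kB list the neutrophil chemokine Cxcl1 rose by 1.22 ± 0.30, and 2 members passed when adjusted over the list alone. Adjusted over the list alone 2 type I interferon genes, 1 macrophage, 2 hypoxia and 1 dissociation stress gene were higher, and 1 hypoxia, 1 fibroblast and 1 cell cycle gene lower.

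In anti-PD-L1 against control 61 genes changed, 30 higher and 31 lower, and all 61 had no overlap between groups, as did 23.5% of all genes tested where chance gives 10%. The Bc1 level was 0.88 ± 0.5 log2 units above control. The count was 97 without control replicate 1, 1 without control replicate 2, and 12, 5 and 18 without anti-PD-L1 replicates 1, 2 and 3. It was 1 with the number of detected genes as a covariate, 30 with the Bc1 covariate, 23 without minP1 replicate 2 and anti-PD-L1 replicate 1, 37 at equal depth, 152 in a fit of the 6 samples, 167 without a filter and 174 with limma voom.

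The third comparison set the combination against control. The gelatinase Mmp9 (chromosome 2, 164940780 to 164955850, plus strand), a neutrophil granule enzyme, rose from 3.39 ± 3.69 to 164 ± 58.8 CPM. This rested on 3 control and 72 combination counts, a ratio of 53.7 with a counting interval of 17.7 to 266.7. The alarmin subunit S100a9 (chromosome 3, 90692632 to 90695721, minus strand) rose from 17.5 ± 19.9 to 174 ± 17.1 CPM (3.11 ± 0.44, adjusted p = 1.98e-05, edgeR). Apoe (chromosome 7, 19696109 to 19699188, minus strand), a lipid carrier made by macrophages, rose from 177 ± 58.9 to 1257 ± 589 CPM, and the antiviral gene Rsad2 (chromosome 12, 26442746 to 26456452, minus strand) from 48.7 ± 23.4 to 322 ± 136 CPM. Mki67 fell from 115 ± 20 to 14.3 ± 7.32 CPM (-2.90 ± 0.45, adjusted p = 4.19e-05). In each of these genes all 3 combination libraries lay beyond every control.

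**Figure D2:**
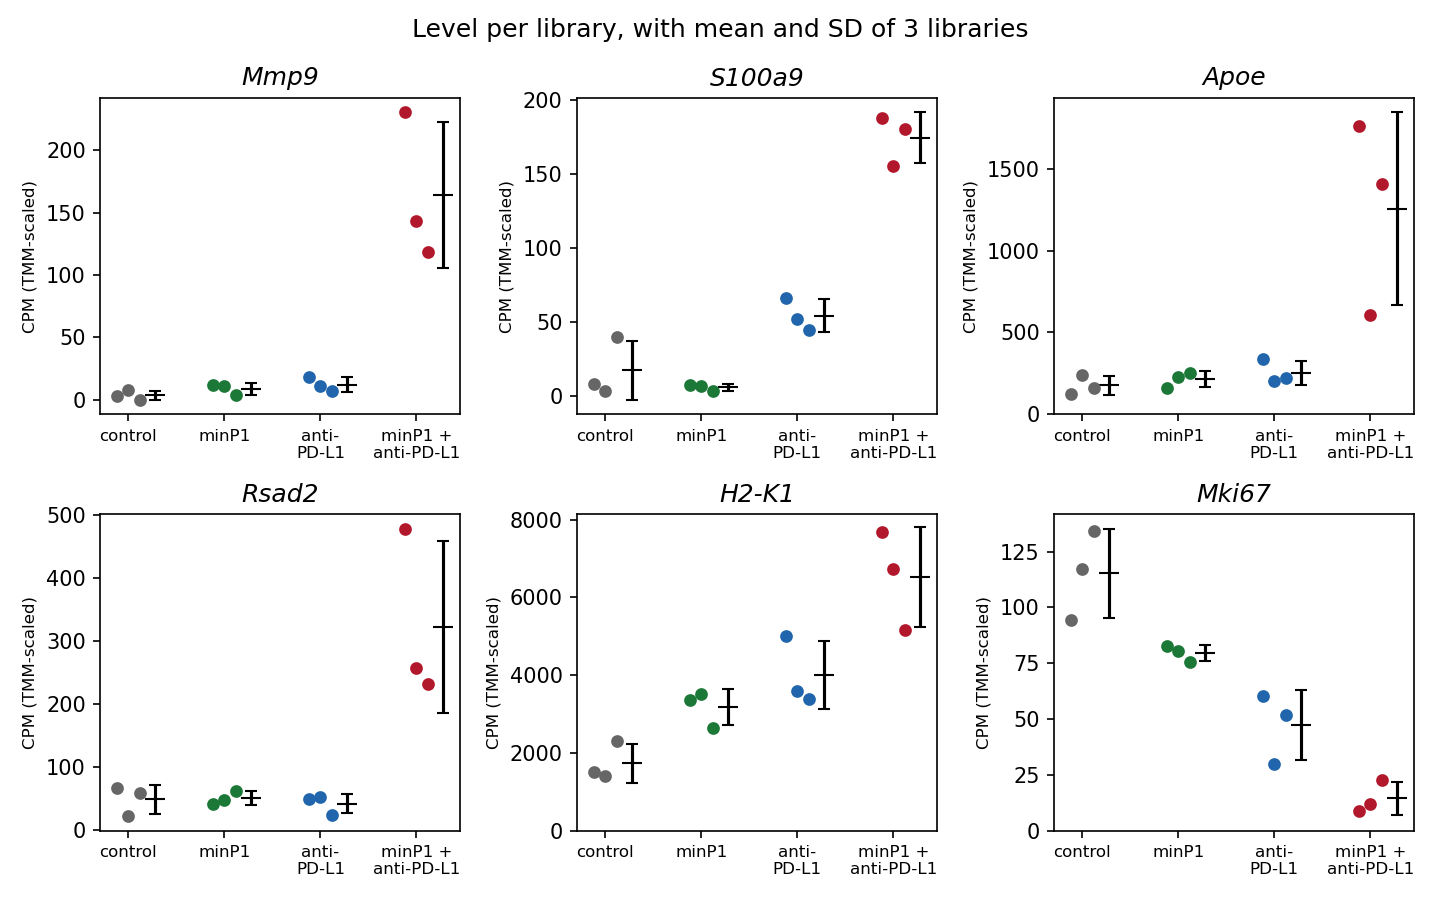
Level in CPM (TMM-scaled, linear axes) of 6 genes in each of the 12 libraries by treatment group, where the bar marks the mean and SD of 3 libraries. Mmp9 lay between 118.5 and 230.5 CPM in the combination and at or under 18.1 CPM in every other library.

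In the same comparison 5 of 7 neutrophil genes rose and 1 fell, and the same numbers held when adjusted over the list alone. Beside Mmp9 and S100a9, the histamine-forming enzyme Hdc rose by 3.18 ± 0.47, while Cxcr2 fell by 1.16 (SE 0.26). S100a8, the partner of S100a9, was not tested and had 2 counts in control and 2 in the combination. The list mean was 1.66 (camera, adjusted p = 0.01; adjusted p = 0.163 with an estimated correlation). Of 9 macrophage genes 6 rose and 1 fell, both over all genes and adjusted over the list alone. Apoe rose by 2.83 ± 0.33, Ms4a7 by 1.59 ± 0.31, the complement subunit C1qc by 1.26 ± 0.27 and arginase Arg1 by 1.11 ± 0.30. The macrophage mean was 0.94 (adjusted p = 0.01; adjusted p = 0.27 with an estimated correlation). Of 7 monocyte genes 4 rose and 0 fell, over all genes and adjusted over the list alone, with Plac8 at 3.43 ± 0.59, F10 at 2.66 ± 0.45, Ly6a at 1.27 ± 0.38 and fibronectin Fn1 at 0.59 ± 0.22. The monocyte mean was 1.18 and the median 0.63 (adjusted p = 0.01; adjusted p = 0.163 with an estimated correlation).

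Some type I interferon and MHC class I genes rose as well. Of the 5 type I interferon genes tested, from a list of 20, 4 rose, both over all genes and adjusted over the list alone, among them Rsad2 (2.64 ± 0.36), Ifi44 (2.24 ± 0.34), Rtp4 (2.07 ± 0.34) and Ifit1 (1.48 ± 0.57). The list mean was 1.46 (camera, adjusted p = 0.01; adjusted p = 0.163 with an estimated correlation). The other 15 had too few counts for the filter, 208 in control and 78 in the combination, and their sum was at -0.17 ± 0.29. Among them Ifit2 went from 24 counts to 2, Oas1a from 14 to 0 and Usp18 from 11 to 0, genes chosen after their values were seen. In the MHC class I list 7 of 13 rose and 1 fell, also when adjusted over the list alone. H2-K1 rose by 1.91 ± 0.25, B2m by 1.76 ± 0.26 and Tap1 by 1.69 ± 0.33, whereas H2-T23, a nonclassical class I gene, fell by 1.75 (SE 0.37). The mean was 0.71 (adjusted p = 0.01; adjusted p = 0.497 with an estimated correlation). Of 11 interferon gamma genes 2 rose, Irf1 (1.28 ± 0.33) and Gbp4 (1.42 ± 0.44), also when adjusted over the list alone, with a list mean of 0.93 (adjusted p = 0.01; adjusted p = 0.497 with an estimated correlation). Without control replicate 1 the adjusted p was 0.0754 for MHC class I and 0.135 for interferon gamma, whose mean was then 0.53, and 1.48 without control replicate 3. In the MHC class II list, which did not pass (mean 0.46, adjusted p = 0.227), 1 of 6 genes rose, also adjusted over the list alone, H2-DMb1 (1.46 ± 0.43), a subunit of the class II peptide editor. That list passed camera with the Bc1 covariate (mean 1.18, adjusted p = 0.00673; adjusted p = 0.261 with an estimated correlation) and with the number of detected genes as covariate (1.26, 0.00481; adjusted p = 0.257 with an estimated correlation).

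Inflammatory and suppressive mediators moved in both directions. In the TLR and NF-kB list 4 of 11 genes rose and 1 fell, also adjusted over the list alone, and the list did not pass (mean 0.36, adjusted p = 0.227, camera). With the Bc1 and detected-gene covariates it passed at a mean of 0.61 (0.049 and 0.0418; adjusted p = 0.18 and 0.23 with an estimated correlation). Cxcl1 rose by 2.25 ± 0.30, Tnf by 3.11 ± 0.62, the prostaglandin synthase Ptgs2 by 1.09 ± 0.25 and the chemokine Ccl4 by 1.17 ± 0.34. Of the 4 tested genes of the immunosuppressive myeloid list, the arginases Arg2 (3.52 ± 0.56) and Arg1 rose, and Vegfa fell by 1.73 (SE 0.54). The pentraxin Ptx3, a soluble pattern receptor, rose by 4.53 ± 0.58, Mmp12 by 4.26 ± 0.44, the lectin Clec10a by 4.02 ± 0.75, the immunoglobulin transporter Pigr by 3.81 ± 0.70 and the inhibitory receptor Cd300a by 3.75 ± 0.65. The T cell checkpoint gene Ctla4 (chromosome 1, 60887000 to 60915832, plus strand) rose from 13.1 ± 14.1 to 142 ± 35.5 CPM (3.24 ± 0.53, adjusted p = 7.5e-05, edgeR), and the costimulatory receptor Tnfrsf9 rose by 1.87 ± 0.44.

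Many genes of glycolysis, matrix and early stress fell one by one, while their lists did not pass camera. In the hypoxia and glycolysis list 8 of 14 genes fell and 2 rose (3 rose and 8 fell adjusted over the list alone). Aldolase Aldoa, whose symbol covers 2 annotated genes (-2.72 ± 0.44), lactate dehydrogenase Ldha (-2.09 ± 0.36) and pyruvate kinase Pkm (-1.75 ± 0.32) were among those that fell. The glucose transporter Slc2a1 rose by 2.24 ± 0.31. The list did not pass camera (mean -0.73, adjusted p = 0.0657) and passed fry (adjusted p = 0.045). Camera passed it with the replicate number as a block (0.0472), with libraries thinned to equal depth (0.032) and without minP1 replicate 2 and anti-PD-L1 replicate 1 (0.0376), and in none of these at an estimated correlation (adjusted p = 0.446, 0.394 and 0.472 with an estimated correlation). Of 7 fibroblast genes 3 fell, also adjusted over the list alone, the matrix protein Sparc (-2.26 ± 0.36), the collagen chain Col1a2 (-0.81 ± 0.21) and the growth factor receptor Pdgfra (-2.05 ± 0.57). The list mean was -0.65 (adjusted p = 0.227 by camera, 0.0222 by fry). Of 14 dissociation stress genes 7 fell and 2 rose, also adjusted over the list alone, and among those that fell were the heat shock gene Hspa1b, which has a near-identical copy (-2.33 ± 0.48), Fos (-1.33 ± 0.28) and Egr1 (-1.14 ± 0.25). The list mean was -0.59 (adjusted p = 0.17 by camera, 0.045 by fry). In the cell cycle list (mean -0.34, adjusted p = 0.469) 3 of 14 genes fell, Mki67, Top2a (-1.37 ± 0.28) and Rrm2 (-1.20 ± 0.37), and the centromere histone Cenpa rose by 1.33 ± 0.38. With the number of detected genes as covariate that list passed as lower (mean -0.67, 0.0315; adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone 2 rose and 4 fell.

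Several genes had few or no counts in the combination. Prpf19 had 83 counts in control and 0 in the combination, at least 12.4-fold lower against the floor over the group. By the same measure Ccser2 was at least 7.4-fold lower, Tinagl1 at least 6.3-fold and Wnt10a at least 4.9-fold. Hbb-b2 went from 107 counts to 1, a ratio of 47.8 with an interval of 8.4 to 1905.1, and the coatomer gene Copb2 from 104 to 1, a ratio of 46.5 with an interval of 8.2 to 1852.2. Selenof fell from 217 to 4 counts. Of 81 ribosomal protein genes, a group chosen after its values were seen and rich in processed copies, 51 fell and 10 rose, from -4.46 (Rpl5) to 1.63.

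In the combination against control 1892 genes changed (34.8%), 896 higher and 996 lower, with a median size of 1.55 log2 units. Groups did not overlap in 1772 of them, and in 45.9% of all genes tested where chance gives 10%. The Bc1 level was 1.24 ± 0.5 log2 units above control, and 782 genes passed with it as a covariate, 724 of them among the 1892. With the number of detected genes as the covariate 407 passed, 391 of them among the 1892. With the Bc1 covariate Mmp9 (5.00), Apoe (2.95), Rsad2 (2.54), S100a9 (3.42), H2-K1 (1.66) and Ctla4 (3.15) still passed, and Ccl4, Cenpa, Hspa1b, Egr1, Vegfa, Pdgfra, Col1a2, Ifit1 and H2-DMb1 did not.

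Totals of the counts of each list were tested in the same fit, where 1 abundant gene can carry a total. In the combination against control the pan-T cell total rose from 60.1 ± 21.5 to 227 ± 57.4 CPM (1.85 ± 0.31, edgeR, adjusted p = 0.000101 over the 28 lists), and the checkpoint total by 1.91 ± 0.37. MHC class I rose by 1.37 ± 0.25, type I interferon by 1.21 ± 0.23, neutrophil by 0.94 ± 0.22, conventional dendritic by 1.29 ± 0.33, monocyte by 0.87 ± 0.22, B and plasma cell by 1.44 ± 0.49 and mast cell, basophil and eosinophil by 1.33 ± 0.45. Hypoxia and glycolysis (-0.78 ± 0.25) and fibroblast totals (-0.61 ± 0.22) fell. CD8 and cytotoxic genes were at 0.28 ± 0.34, NK at 0.31 ± 0.28, regulatory and helper T at 0.08, macrophage at -0.13 ± 0.24, mature dendritic at 0.64, plasmacytoid dendritic at -0.06, MHC class II at 0.40, interferon gamma at 0.81, TLR and NF-kB at 0.30, immunosuppressive myeloid at 0.52 and cell cycle at -0.11, none passing. The other tissues' lists also did not pass, with epithelial and carcinoma at 0.58 ± 0.5, endothelial at 0.59, skeletal muscle at 0.03, adipocyte and keratinocyte at 1.56 ± 0.64, erythroid and platelet at -0.51 and dissociation stress at -0.20. In the macrophage total Spp1, chosen after its values were seen, held 7865 of 9213 control counts and 2027 of 3569 combination counts, and it fell (-0.752 ± 0.262, adjusted p = 0.0289). Anti-PD-L1 against control gave higher totals for pan-T (1.29 ± 0.31), MHC class I (0.95 ± 0.24) and monocyte genes (0.76 ± 0.22), and minP1 against control gave none (smallest adjusted p = 0.163).

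Single genes that were also tested alone held much of several totals. Ctla4 held 65 of 97 checkpoint counts in the combination and 16 of 62 in control, and Clec10a 43 of 74 conventional dendritic counts and 6 of 73. Gata2 held 32 of 39 counts of the mast cell list and 27 of 34, and Pax5 18 of 35 B and plasma cell counts and 8 of 30. In the neutrophil list S100a9 held 80 of 341 counts in the combination and 22 of 418 in control, and Mmp9 72 and 3. Counts summed over only the members not tested alone, a test chosen after the data were seen, did not pass for these lists or for other lists with higher totals except pan-T cell. The filter keeps genes that are high in a group and so sorts members partly by their change, and these sums therefore do not decide how many members rose. They were at 0.73 ± 0.42 for checkpoint, 0.04 ± 0.45 for conventional dendritic, 1.11 ± 0.95 for mast cell, 0.86 ± 0.58 for B and plasma cell, -0.17 ± 0.29 for type I interferon, 0.33 ± 0.99 for neutrophil (11 counts in control and 6 in the combination), 0.10 ± 0.65 for MHC class I and 1.21 ± 0.54 for monocyte (adjusted p = 0.162). The same test passed for 13 pan-T cell genes with 33 control and 55 combination counts (2.0 ± 0.44, adjusted p = 0.00393, edgeR) and for 8 regulatory and helper T genes with 19 and 27 (1.67 ± 0.52, adjusted p = 0.0324). The sum of 8 erythroid and platelet genes fell, from 114 counts to 12 (-2.06 ± 0.49, adjusted p = 0.00393). In the other 5 comparisons no such sum passed (smallest adjusted p = 0.0503), among them pan-T cell in anti-PD-L1 against control (1.28 ± 0.45, adjusted p = 0.121).

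Adding minP1 to anti-PD-L1 was measured by the combination against anti-PD-L1. Mmp9 rose by 3.79 ± 0.53, Rsad2 by 2.95 ± 0.39 and Apoe by 2.32 ± 0.33 (adjusted p = 0.000365 for each, edgeR), with all 3 combination libraries above every anti-PD-L1 library for Rsad2. Of 7 neutrophil genes 3 rose over all genes and 4 adjusted over the list alone, among them Hdc (2.03 ± 0.44) and S100a9 (1.70 ± 0.41). The neutrophil mean was 1.04 (camera, adjusted p = 0.00249; adjusted p = 0.144 with an estimated correlation). Of 9 macrophage genes 4 rose (5 higher and 1 lower adjusted over the list alone), with Ms4a7 at 1.39 ± 0.32 and Mrc1 (chromosome 2, 14229392 to 14332057, plus strand) at 1.37 ± 0.30. The macrophage mean was 0.73 (adjusted p = 0.00345; adjusted p = 0.271 with an estimated correlation). Of 5 type I interferon genes 2 rose, Rsad2 and Ifi44 (1.10 ± 0.33), and 3 adjusted over the list alone, with a mean of 1.13 (adjusted p = 0.00315; adjusted p = 0.149 with an estimated correlation).

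Glycolysis genes fell in this comparison. Ldha (-1.67 ± 0.36), Pkm (-1.35 ± 0.33), Pgk1 (-1.12 ± 0.26) and Tpi1 (-1.12 ± 0.31) fell. Of 14 hypoxia and glycolysis members 5 fell over all genes, while adjusted over the list alone 7 fell and 1 rose. The mean was -0.74 (camera, adjusted p = 0.00345; adjusted p = 0.588 with an estimated correlation). In the dissociation stress list Hspa1b (-2.16 ± 0.49), Fos (-1.14 ± 0.29) and Jun (-1.02 ± 0.30) fell, 3 of 14 members. Adjusted over that list alone 5 fell and 1 rose. Its mean was -0.52 (adjusted p = 0.0433; adjusted p = 0.588 with an estimated correlation), and the call was lost without anti-PD-L1 replicates 1 or 2 (0.131 and 0.104) or combination replicates 1, 2 or 3 (0.069, 0.0573 and 0.0707). Other genes that rose were Cd24a (3.09 ± 0.61), Serpinb2 (2.69 ± 0.72), Cd300a (2.67 ± 0.62), Ptx3 (2.36 ± 0.50), Tnf (2.02 ± 0.60) and Arg2 (1.94 ± 0.51). H2-T23 (-1.47 ± 0.39), the NF-kB inhibitor Tnfaip3 (-1.28 ± 0.37) and Sparc (-1.29 ± 0.38) fell. Copb2 went from 32 counts to 1, a ratio of 20.3 with an interval of 3.4 to 825.4, and Ccser2 was at least 3.8-fold and Wnt10a at least 3.2-fold lower.

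Over all genes 378 changed between the combination and anti-PD-L1, 163 higher and 215 lower, 353 of them without overlap between groups (27.3% of all genes, 10% by chance). H2-K1 was at 0.71 ± 0.25 (adjusted p = 0.0811). Lists that did not pass were monocyte (mean 0.34), MHC class II (0.14), cell cycle (-0.21) and fibroblast (-0.33), and MHC class I (mean -0.06, median 0.06), interferon gamma (mean -0.09, although camera ranked it above other genes) and TLR and NF-kB (mean -0.01, median 0.06), whose signs differed between measures. In the other lists 2 monocyte and 4 TLR and NF-kB genes were higher when adjusted over the list alone, and 3 TLR and NF-kB, 2 cell cycle, 1 MHC class I and 1 fibroblast gene lower. Totals passed for neutrophil (1.13 ± 0.23), type I interferon (1.12 ± 0.23) and conventional dendritic genes (1.25 ± 0.34), where Clec10a alone was at 2.15 ± 0.66. The macrophage total was at -0.19 ± 0.24. The Bc1 level differed by 0.36 ± 0.5. The count was 126 and 100 without anti-PD-L1 replicates 2 and 3, 79 and 198 without combination replicates 1 and 2, 624 without minP1 replicate 2 and anti-PD-L1 replicate 1, and 636 with limma voom.

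Adding anti-PD-L1 to minP1 was measured by the combination against minP1. S100a9 rose by 4.76 ± 0.56 and Mmp12 by 3.69 ± 0.43 (adjusted p = 1.11e-05 for both, edgeR), Mmp9 by 4.19 ± 0.54, Cd24a by 4.22 ± 0.68, Arg2 by 4.13 ± 0.63 and the neutrophil chemokine Cxcl5 by 3.52 ± 0.70. Of 7 neutrophil genes 3 rose (4 higher and 1 lower adjusted over the list alone), with a mean of 1.59 (camera, adjusted p = 0.0022; adjusted p = 0.138 with an estimated correlation). Of 9 macrophage genes 5 rose and 1 fell, also adjusted over the list alone, among them Apoe (2.54 ± 0.33), Ms4a7 (2.25 ± 0.33) and Mrc1 (2.02 ± 0.31), with a mean of 0.99 (adjusted p = 0.00289; adjusted p = 0.16 with an estimated correlation). Of 5 type I interferon genes 3 rose, also adjusted over the list alone, Rsad2 by 2.62 ± 0.37, Rtp4 by 1.57 ± 0.34 and Ifi44 by 1.29 ± 0.32, with a mean of 1.13 (adjusted p = 0.0105; adjusted p = 0.16 with an estimated correlation). In the monocyte list Plac8 rose by 2.81 ± 0.58, the 1 member of 7 that passed, also adjusted over the list alone (mean 0.79, adjusted p = 0.0341; adjusted p = 0.16 with an estimated correlation). The monocyte call was lost without minP1 replicate 1 (0.0738) and without combination replicates 1 or 2 (0.0638 and 0.0545).

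The hypoxia and glycolysis list was lower as well (mean -0.73, camera, adjusted p = 0.0352; adjusted p = 0.684 with an estimated correlation), and did not pass fry (0.0646). Aldoa (-2.27 ± 0.46), Ldha (-2.01 ± 0.36) and Pkm (-1.51 ± 0.33) fell, and Slc2a1 rose by 1.59 ± 0.30. Of 14 members 7 fell and 2 rose, or 8 and 2 adjusted over the list alone. The list call was lost without minP1 replicates 1 or 3 (0.0803 and 0.111) and without combination replicates 1 or 2 (0.0691 and 0.0574). Mki67 (-2.36 ± 0.47), Top2a (-1.44 ± 0.28) and Egr1 (-1.23 ± 0.25) fell. In the MHC class I list H2-K1 (1.04 ± 0.25) and B2m (1.05 ± 0.26) rose, H2-T23 (-1.41 ± 0.38) and Tap2 (-1.02 ± 0.34) fell, and the list did not pass (mean 0.07, adjusted p = 0.54; 3 higher and 3 lower adjusted over the list alone). The other lists that did not pass had means of 0.07 for MHC class II, 0.07 for interferon gamma, 0.31 for TLR and NF-kB, -0.25 for cell cycle, -0.46 for fibroblast and -0.45 for dissociation stress. With the Bc1 covariate interferon gamma passed at a mean of 0.57 (0.042; adjusted p = 0.566 with an estimated correlation). When adjusted over the list alone 4 TLR and NF-kB, 1 cell cycle and 1 dissociation stress gene were higher, and 3, 2 and 7 genes of these lists and 2 fibroblast genes lower. Totals passed for neutrophil (1.23 ± 0.23), type I interferon (1.0 ± 0.23), checkpoint (1.30 ± 0.36), pan-T (1.0 ± 0.30), MHC class I (0.66 ± 0.24), mature dendritic (0.75 ± 0.27), conventional dendritic (0.84 ± 0.32) and adipocyte and keratinocyte genes (1.75 ± 0.67), and for hypoxia (-0.72 ± 0.25). Fabp4 held 22 of the 24 adipocyte and keratinocyte counts in the combination and did not pass alone (1.74 ± 0.74, adjusted p = 0.0943). The macrophage total was at -0.17 ± 0.24.

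Of all genes 1088 changed between the combination and minP1, 500 higher and 588 lower, 1030 of them without overlap (37.5% of all genes, 10% by chance). Prpf19 was at least 3.3-fold, Ccser2 at least 5.7-fold, Wnt10a at least 5.4-fold and Tinagl1 at least 4.3-fold lower. The Bc1 level was 0.88 ± 0.5 log2 units higher. With it as a covariate 601 genes passed, and 292 with the number of detected genes. The count was 706 and 592 without minP1 replicates 1 and 3, and 615 and 702 without combination replicates 1 and 2.

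The interaction asked whether the combination differed from the sum of the effects of each treatment on the log2 scale, a question posed by the series title. Genes of neutrophils, macrophages and the type I interferon response lay above that sum, and genes of MHC class I, interferon gamma and glycolysis below it, as lists. Only 7 of 16 neutrophil, 9 of 16 macrophage and 5 of 20 type I interferon genes passed the filter on low counts. That filter keeps genes that are high in a group, such as the combination, so it may itself raise these means. How far it does was not tested. The 6 calls were lost with fry, and the closest, neutrophil, was at adjusted p = 0.0946 with an estimated correlation. No gene alone passed. Mrc1 (2.26 ± 0.43) and Rsad2 (2.93 ± 0.57) came closest (adjusted p = 0.0705 for both, edgeR). Mrc1 stood at 204 ± 62.7 CPM in control, 111 ± 31.1 in minP1, 173 ± 32 in anti-PD-L1 and 452 ± 156 in the combination.

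Neutrophil genes had a mean interaction of 0.97 (camera, adjusted p = 0.000652, and 0.0946 with an estimated correlation). Their median was 0.42, with S100a9 at 3.36 ± 0.82, so the mean rests partly on that gene. The list total gave 1.42 ± 0.32 (edgeR, adjusted p = 0.00424 over the 28 lists). That total was 384 ± 47.8 CPM in control, 315 ± 33.5 in minP1, 337 ± 53.5 in anti-PD-L1 and 739 ± 57.7 in the combination, and no other list total passed. Of the neutrophil counts S100a9 held 80 of 341 in the combination and 22 of 418 in control. Mmp9 held 72 and 3 of them, so the neutrophil total rests largely on these genes and does not show a rise across the list. Macrophage genes had a mean of 0.78 (adjusted p = 0.00172; adjusted p = 0.282 with an estimated correlation), with Ms4a7 at 2.06 ± 0.47 and Apoe at 2.03 ± 0.47, while the macrophage total was at -0.24 ± 0.34, of the opposite sign. Type I interferon genes had a mean of 0.80 and a median of 0.37 (camera, adjusted p = 0.0173, and 0.282 with an estimated correlation). MHC class I had a mean of -0.70 (adjusted p = 0.00172; adjusted p = 0.44 with an estimated correlation), with the immunoproteasome subunit Psmb10 at -1.27 ± 0.40 and Tap2 at -1.37 ± 0.46. Interferon gamma had a mean of -0.96 (adjusted p = 0.00778; adjusted p = 0.543 with an estimated correlation), with Irf1 at -1.0 ± 0.45. Hypoxia and glycolysis had a mean of -0.74 (adjusted p = 0.00172; adjusted p = 0.44 with an estimated correlation), with Ldha at -1.59 ± 0.48 and Pgk1 at -1.09 ± 0.36. Over all genes 0 members passed. Adjusted over the list alone these numbers were 1 neutrophil, 4 macrophage and 1 type I interferon gene higher, 2 MHC class I and 2 hypoxia genes lower, and 0 interferon gamma genes.

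**Figure D3:**
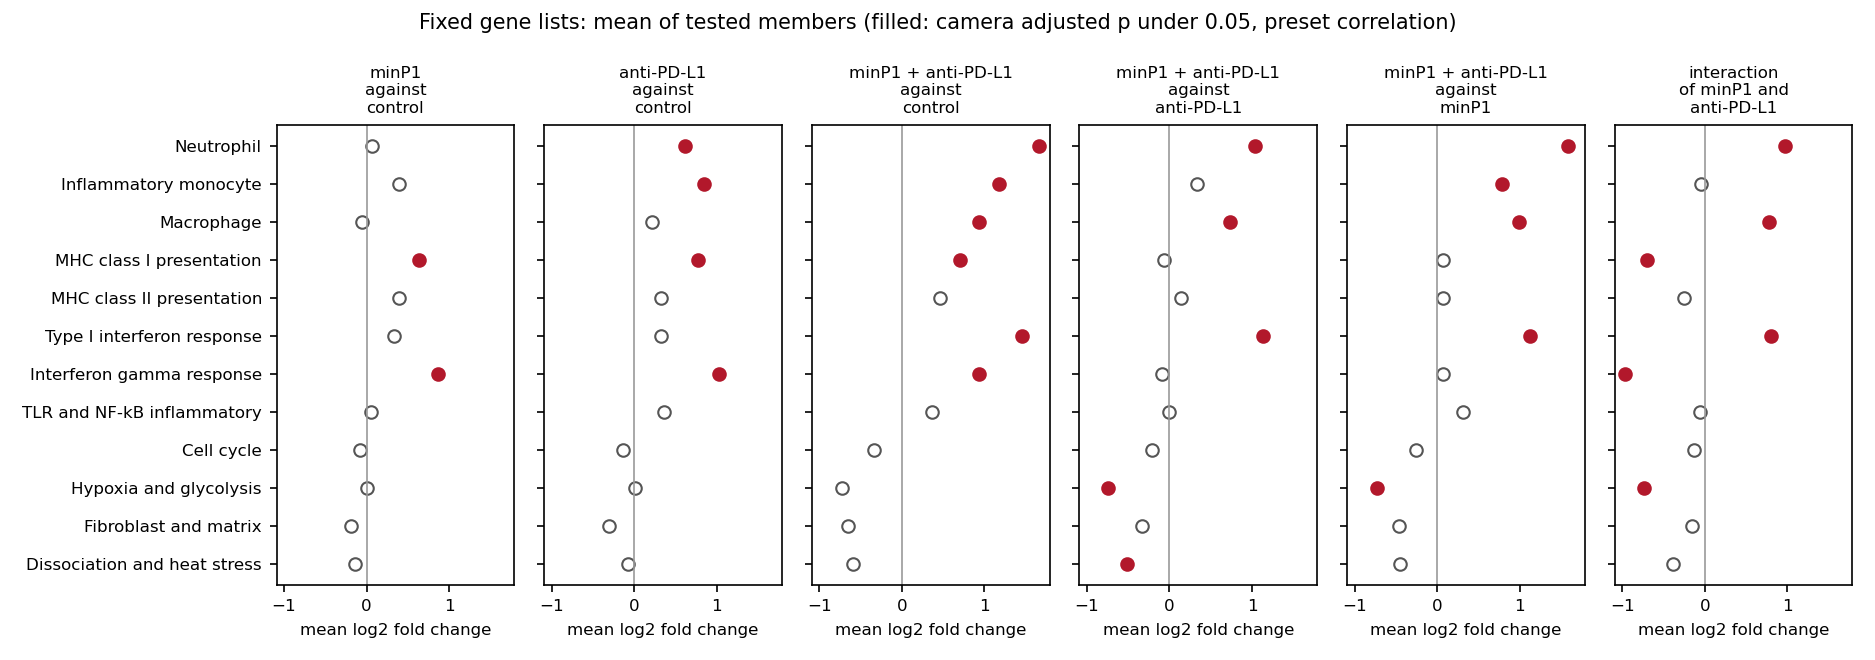
Mean log2 fold change of the tested members of each of the 12 lists in each of the 6 comparisons, where filled points passed camera with its preset correlation. With an estimated correlation no point would be filled.

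In the interaction edgeR called 0 of 5443 genes, with 600 at an unadjusted p under 0.05 (272 by chance), while DESeq2 called 20 among the 1011 genes to which it gave an adjusted p, and limma voom 10. The count was 37 without a filter, 2 with upper-quartile scaling, 35 with the Bc1 covariate, 6 with the number of detected genes, and 62, of which 52 lower, without minP1 replicate 2 and anti-PD-L1 replicate 1. It was 6 without minP1 replicate 2, 5 without anti-PD-L1 replicate 1, 1 and 2 without control replicates 2 and 3, and 1 and 3 without combination replicates 2 and 3. The replicate number as a block also took the count above 0, as given with the processing below. The type I interferon call was lost without control replicate 3 (0.0638), minP1 replicate 1 (0.0906) or anti-PD-L1 replicate 3 (0.0682). The interferon gamma call was lost without control replicate 1 (mean -0.50, 0.121) or minP1 replicate 3 (0.062), and its mean was -1.50 without control replicate 3. The MHC class I mean was -0.46 without control replicate 1. The monocyte list (mean -0.05) and the TLR and NF-kB list (mean -0.06) did not pass, and camera ranked both above other genes against the sign of their means. Of the TLR and NF-kB genes 1 was higher and 1 lower when adjusted over the list alone, with 0 over all genes. MHC class II (-0.25), cell cycle (-0.13), fibroblast (-0.15) and dissociation stress (-0.38) did not pass either. Without minP1 replicate 2 and anti-PD-L1 replicate 1 dissociation stress passed (-0.52, 0.034; adjusted p = 0.49 with an estimated correlation).

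The changes from each treatment ran partly alongside each other. Of the 61 genes changed by anti-PD-L1 alone, 57 also changed in the combination, 27 higher and 30 lower, where independent lists would share 4.9 and 5.7. Simulated unchanged groups against shared controls shared 0 on average. With no gene changed almost none is called, so that 0 was fixed in advance and is no reference for the overlap. Across the 5443 genes, which are not independent replicates, the fold changes of anti-PD-L1 and of the combination against control correlated at r = 0.79 (0.40 in simulated unchanged groups) with a covariance of 0.593 (simulated 0.078, difference 0.515). For minP1 and the combination against control r was 0.61 (simulated 0.41) with a covariance of 0.344 (simulated 0.077, difference 0.267). For minP1 and anti-PD-L1 r was 0.69 (simulated 0.45) with a covariance of 0.201 (simulated 0.077, difference 0.124). The 3 controls cannot be split into parts of at least 2, so part of the excess may come from sharing them. The simulation drew each gene independently, so it does not show how far r varies where many genes move together within a library. Comparisons with no library in common gave r = 0.64 for anti-PD-L1 against control with the combination against minP1, which shared 23 higher and 26 lower genes (2.8 and 3.3 for independent lists). They gave r = 0.38 for minP1 against control with the combination against anti-PD-L1. The Bc1 level differed by 0.88 ± 0.5 log2 units in both comparisons behind r = 0.64. It differed by 0.36 ± 0.5 in both behind r = 0.38. A library property measured by that level could therefore contribute to these correlations, and this was not tested.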

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

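The tests of the Bc1 level against the changes between the combination and control, and the test of near-identical copies, were chosen only after those results were seen. So were the tests of list totals.

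As lists, neutrophil and macrophage genes lay above the sum of the separate treatments, with mean interactions of 0.97 and 0.78 log2 units. Their medians were 0.42 and 0.56. Only members that passed the filter on low counts entered, and that filter keeps genes that are high in a group. Part of these means may therefore come from the filter, which was not tested. The test was of the difference between the effects of minP1 with and without anti-PD-L1. Neither list held with an estimated correlation (camera, adjusted p = 0.0946 and 0.282) or with fry (0.0747 and 0.122). Totals of the lists parted, with 1.42 ± 0.32 for neutrophil and -0.24 ± 0.34 for macrophage, so the macrophage part depends on the measure. Spp1 alone held 85.4% of control and 56.8% of combination counts of the macrophage total. In the neutrophil total S100a9 held 22 of 418 control and 80 of 341 combination counts, and Mmp9 3 and 72. The neutrophil total therefore rests largely on these genes. One library does not account for the neutrophil call, since the adjusted p of the neutrophil list was at most 0.00383 without each of the 12 libraries in turn. A higher share of leukocytes of every kind could give the same pattern and stays open: 14 genes fixed as general leukocyte genes had a median interaction of 0.35 with quartiles of -0.21 and 0.90, 10 of them above 0. The set includes genes mainly of myeloid cells, such as Lyz2, Cybb and Fcer1g. It therefore cannot tell such a share from a change of myeloid cells alone. The Bc1 level as a covariate left the neutrophil mean at 0.97, but the Bc1 level has an interaction of its own of 0 ± 0.7, so this covariate could not have moved it and the bound written for the test was wrong.

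Between the combination and control 1892 genes changed. The tables argue against unequal depth as the whole cause, since 70.6% of these genes were also called with all libraries thinned to the smallest total. A library property that varies within groups, measured by the Bc1 level, left 80.7% of the median change (1.55 to 1.25; 73.5% to 84.4% without each library in turn), although the calls came down to 782 with a median SE of 0.49 in place of 0.40; for 17 changed neutrophil, macrophage and type I interferon genes it left 95.1% (1.66 to 1.58, 81.2% to 100.3%), and 12 still passed. Reads shared with near-identical copies do not account for most of it, since genes with no copy were called 80.8% as often as genes with one (34.0% of 4908 against 42.1% of 311). Of 77 genes that match 4 or more others 48.1% were called and 40.3% were called lower, against 17.6% called lower with no copy. Copies may therefore add to the lower calls. These tests could not detect a library property confounded with treatment. Ribosomal RNA took 3.04% ± 0.753 of control counts and 1.03% ± 0.172 of combination counts. Of 81 ribosomal protein genes 51 fell and 10 rose, at 16.9% ± 1.28 of control and 15.6% ± 1.47 of combination counts. A response to the combination may be a part of the pattern, as a hypothesis. Nothing tested here separates it from a library property confounded with treatment or from a change in cell shares, and both stay open.

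With minP1 alone the MHC class I and interferon gamma lists were higher with no gene passing. One library does not account for the MHC class I call, which held at an adjusted p of at most 0.0012 without each of the 6 libraries, although its mean was 0.42 without control replicate 1. A higher share of leukocytes of every kind would need general leukocyte genes to be higher, and their median was -0.15 (quartiles -0.40 and 0.12, 9 of 14 below 0), under the list mean of 0.64. As the set includes genes mainly of myeloid cells, a higher share of lymphocytes alone is not covered. A response of interferon-regulated genes to minP1 may be behind the pattern, as a hypothesis, but the call rests on the preset correlation (adjusted p = 0.406 for MHC class I and 0.414 for interferon gamma with an estimated one), and other divisions of the 6 samples called up to 6 lists against the real 2.

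The other interactions were also marked by the test of the difference between the effects of minP1 with and without anti-PD-L1. The mean was -0.70 for MHC class I, -0.96 for interferon gamma, 0.80 (median 0.37) for type I interferon and -0.74 for hypoxia and glycolysis. None of them held with an estimated correlation (adjusted p = 0.44, 0.543, 0.282 and 0.44).

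Other divisions of the samples were set beside each count. With 3 samples against 3 there are 10 divisions, too few for a share under 0.05. The real and highest other gene counts were 0 and 1 for minP1 against control (10 divisions at least as large, the real one included), 61 and 0 for anti-PD-L1 (1), 1892 and 0 for the combination (1), 378 and 0 for the combination against anti-PD-L1 (1), and 1088 and 78 for it against minP1 (1). For lists they were 2 and 6 (7 divisions), 4 and 7 (3), 6 and 8 (2), 5 and 3 (1), and 5 and 4 (1) in the same order. For the interaction 100 of the divisions of the 12 samples into 4 groups of 3 were drawn, the real one included. Of these, all 100 called at least the real 0 genes, which no division can fail to do, and the highest other called 1059. At least the real 6 lists were called by 10, and the highest other called 9. The high counts of other divisions point to a structure of the samples, since a division that mixes treatments turns treatment effects into an interaction. Such divisions are therefore no reference without a change, and chance is not excluded for the interaction.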

How the results depend on the processing

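The Bc1 and detected-gene covariates, the joint removal of minP1 replicate 2 and anti-PD-L1 replicate 1, the removal of abundant genes and the list totals were chosen after the data were seen. The comparisons are ordered as minP1, anti-PD-L1 and the combination against control, the combination against anti-PD-L1 and against minP1, and the interaction. Gene counts of 0, 61, 1892, 378, 1088 and 0 moved over 1.5 times as follows, and the cause was not tested unless given. Without a filter, which tests 19921 genes, they were 51, 167 and, for the interaction, 37. DESeq2 gave 1 for minP1 and 20 for the interaction, where it left 4432 adjusted p-values undefined. Limma voom gave 174 for anti-PD-L1, 636 for the combination against it and 10 for the interaction. Upper-quartile scaling gave 2 for the interaction. Thinning gave 37, and the 6-sample fit 152, for anti-PD-L1. The Bc1 covariate gave 1, 30, 782, 601 (against minP1) and 35, and the detected-gene covariate 1 (anti-PD-L1), 407, 292 (against minP1) and 6. The joint removal gave 23 (anti-PD-L1), 624 (against anti-PD-L1) and 62. Leaving out 1 library gave 0 to 5, 1 to 97, 1391 to 1851, 79 to 474, 592 to 1308 and 0 to 6. The interaction was not run on fewer groups, since it needs all 4.

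The replicate number as a block gave 173 genes for anti-PD-L1 against control and 16 for the interaction, and ended no call of a list or named gene. In the combination against control it added hypoxia and glycolysis as a lower list (adjusted p = 0.0472 against 0.0657). The labels do not say that equal numbers share anything, and pairing was not excluded. Of 18 same-numbered pairs 9 correlated above 0.1 (-0.137 to 0.211), and 7 of 12 libraries correlated best with their own number. This is a hint of pairing from the data only. Called lists numbered 2, 4, 6, 5, 5 and 6. With an estimated correlation they were 0 in each comparison. With fry they were 0, 1, 9, 3, 4 and 0 in the same order. The Bc1 covariate gave 7 for anti-PD-L1. Lists gained a call 22 times over scaling, block, thinning, covariates, joint removal and removal of abundant genes, and 0 of these passed with an estimated correlation (smallest adjusted p = 0.0973). Those from the detected-gene covariate were MHC class II for minP1 (0.63, 0.00425) and anti-PD-L1 (0.92, 0.00124), TLR and NF-kB (0.55, 0.00668) and cell cycle (-0.37, 0.016) for anti-PD-L1, and MHC class II, TLR and NF-kB and cell cycle for the combination (1.26, 0.61 and -0.67). Thinning added type I interferon for minP1 (0.53, 0.0262), TLR and NF-kB for anti-PD-L1 (0.41, 0.0494) and hypoxia for the combination (-0.68, 0.032). The joint removal added MHC class II for minP1 (0.51, 0.0441), TLR and NF-kB for anti-PD-L1 (0.48, 0.0234), hypoxia for the combination (-0.69, 0.0376) and dissociation stress for the interaction (-0.52, 0.034). Leaving out 1 library gave 2 to 5, 3 to 6, 4 to 7, 4 to 5, 3 to 5 and 5 to 7. The 5 for minP1 came without control replicate 3 and a 4 without minP1 replicate 2, and the 3 for the combination against minP1 without minP1 replicate 1 or combination replicates 1 or 2.

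List totals turned the sign of the macrophage list. Its means were 0.94, 0.73, 0.99 and 0.78 in the combination against control, against anti-PD-L1, against minP1 and in the interaction, and its totals -0.13, -0.19, -0.17 and -0.24, none passing. Spp1 alone held 85.4% of the control counts and 56.8% of the combination counts of that total, so the total largely follows Spp1. No called list reversed with median-of-ratios scaling, the replicate block, the Bc1 covariate, an estimated correlation or fry. No named gene that passed reversed with median-of-ratios scaling, the replicate block, or DESeq2 where it gave an adjusted p. Nor did any of them reverse in the fit without 1 library that had the highest adjusted p. Reversal was not checked under the other alternatives. Calls of named genes numbered 192, with a gene counted once in each comparison where it passed. Of these, 192 held with median-of-ratios scaling and 160 with DESeq2 (4 were lost, the others had no adjusted p). In every fit without 1 library 111 held, and 81 were lost in at least 1. Calls of the 12 tested lists numbered 28 over the 6 comparisons, with a list counted once in each comparison where it passed. Of these 28 calls, 28 held with median-of-ratios scaling, 26 with the Bc1 covariate, 13 with fry and 20 without each library. Upper-quartile scaling put the median of all genes at -0.113 for the combination against control and -0.126 against minP1. Depth was lowest at 133917 counts, and several immune genes named in advance had too few counts for the filter.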

Other observations

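The tests of globins, ribosomal protein and mitochondrial genes, the Bc1 covariate, GC content and length, and the deviations of libraries within groups were chosen after the results were seen. Of the globins, chosen after their values were seen, Hbb-b1 went from 184 ± 105 to 10 ± 11.5 CPM (-4.09 ± 0.64, edgeR, adjusted p = 4.87e-05) and Hbb-b2 from 95.9 ± 47.3 to 1.89 ± 3.27. The alpha globins were at 893 ± 296 and 596 ± 283 CPM for Hba-a1 (-0.49 ± 0.42, adjusted p = 0.382) and 910 ± 267 and 636 ± 337 CPM for Hba-a2 (-0.42 ± 0.45, adjusted p = 0.491). Both pairs are near-identical copies, and Hba-a1 and Hba-a2 passed with the Bc1 covariate (-1.71 and -1.73). Red cells carry both chains, and the labels record no removal of them.

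Ribosomal protein genes, also chosen after their values were seen, had a median of -1.25 over 81 genes in the combination against control, -0.24 with anti-PD-L1 and -0.15 with minP1. Their share of all counts was 15.6% ± 1.47 in the combination and 16.9% ± 1.28 in control, so the median gene and the total differ. Of the 13 mitochondrial genes 10 fell and 1 rose in the combination (median -1.35), while their share of counts was 1.23% ± 0.283 there and 1.38% ± 0.221 in control. Of 14 general leukocyte genes 5 rose in the combination, Cybb (2.00), Rac2 (1.92), Cytip (1.80), Itgb2 (1.45) and Laptm5 (1.07), and 2 fell, Lyz2 (-1.36) and Lcp1 (-1.10).

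Within groups some libraries deviated along the change of the combination. Across 5443 genes, which are not independent replicates, the deviation of minP1 replicate 2 from its group correlated with that change at 0.45 and that of anti-PD-L1 replicate 1 at 0.40. The other minP1 libraries gave -0.25 and -0.32, and the other anti-PD-L1 libraries -0.20 and -0.31, as deviations within a group sum to 0. With the Bc1 level as covariate the MHC class II genes Cd74 (1.78), H2-Aa (1.82) and H2-Ab1 (1.48) passed in the combination against control (adjusted p = 0.00531, 0.00432 and 0.00896), and without it they did not. Neither GC content nor length tracked the change of the combination, with Spearman correlations across genes of 0.09 and 0.049.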
